A study of Mus musculus with 2 samples.

How the data were processed

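DNase-seq libraries from right cerebral cortex of male B6CASTF1/J mice aged 18 to 20 months were analysed from the processed files of the series. There was 1 group with 2 biological replicates, named replicate 1 and replicate 2 by the biological replicate number in the labels. The labels give the replicates separate tissue sample entries and the same donor entry, and do not say whether the pieces came from separate animals, so the spread between replicates may be technical in part. All values of spread are the SD over these 2 libraries unless stated otherwise.

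Peaks, false discovery rates and footprints were called by the authors on mouse build mm10, in each library alone and not on pooled reads. Aligner, peak caller and versions are not given in the sources used here. The peak height is a signal that the authors scaled to the depth of the library before it was deposited. Within a tolerance of 0.05 of a step, all heights below 5 were whole multiples of a step of 0.00727 in replicate 1 and 0.00812 in replicate 2. The scale factor is not stated. The false discovery rates (q-values) of the FDR cut rate files were computed by the authors per stretch of bases and deposited for values up to 0.05. The score of the footprint files, as deposited by the authors, was constant in every line and was not used, so only footprint positions entered the analysis. Each library had 2 deposited peak lists. In the shorter one every peak held a base with a false discovery rate up to 0.001, and in the longer one every peak held a base with a rate up to 0.05. The shorter list was used throughout. No file was labelled as a hotspot list, so the longer list took the place of the broader list chosen as an alternative.

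The tests, gene lists, consensus sequences and alternative settings were chosen before the data were examined, except where the closing part names a later choice. Overlap meant at least 1 bp in common. Chance overlap came from 100 seeded placements of a list shifted at random along each chromosome. Peaks of both replicates were merged into elements, and an element with peaks of both was called shared. Promoters were windows of 500 bp on either side of any of 93513 annotated transcription starts of protein-coding genes (GENCODE vM21). Other classes were assigned by peak centre. A promoter was called open when a peak overlapped any window of its gene in each replicate, not always the same window. Its height was that of the largest overlapping peak. After 54 symbols used by more than 1 gene were left out, 21884 genes were tested. Of 568 members of the 32 lists, 562 matched an annotated gene.

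Open promoters of each list were compared with those of all other genes by a two-sided Fisher's exact test. Distal elements were shared elements outside promoters with their midpoint in the gene body or within 10 kb on either side. The median number per 10 kb was ranked among 10000 seeded random lists of equal size matched on gene length in 20 bins, which gave a two-sided permutation p. Open promoters were also ranked among random lists matched on CpG content of the promoter in 10 bins. That content was taken at the outermost start of each gene, and the number of starts was not matched. Each of these tests was adjusted by the Benjamini-Hochberg method over the 32 lists, with a threshold of 0.05. Footprints inside peaks were padded by 5 bp on either side and searched on both strands for 28 consensus sequences. Windows of equal width in the same peaks that touched no footprint were the control, compared by Fisher's exact test and adjusted over the 28 sequences in each replicate. Footprints for which no such window was found were left out. Odds ratios had 0.5 added to each count, and intervals of ratios are exact. Where no control window held a sequence, 3 counts were taken as the floor. Genes, elements and footprints are not replicates, so each p describes these 2 libraries.

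Named genes followed a fixed rule. For each list these were the 3 members with the greatest promoter height, the 2 with the most distal elements and the first 2 in alphabetical order of those without a promoter peak in either replicate. Over all genes they were the 10 with the most distal elements, the 10 with the most per 10 kb among genes with at least 10, and the 10 with the greatest promoter height. Single peaks were the 5 highest shared ones and the 3 highest found in only 1 replicate, in each direction. The 8 consensus sequences with the largest odds ratios and those of blood and liver factors were described in full. Some genes that this rule names are not reported here.

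Alternatives were windows of 250 and 1000 bp, the gene body alone or with 50 kb on either side, 50% reciprocal overlap, the higher 50% of each list by height, equal numbers of peaks, the longer list, promoters left out of the correlation, either replicate left out, CpG matching, other padding, shuffled footprint bases as the control, footprints of both replicates only, and chromosome lengths without unknown bases. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Overlaps were computed in numpy in place of bedtools and were checked against a direct comparison on simulated intervals, with 100% equal. The tests were run on 20 simulated data sets with 8 of 32 lists changed. With 30.0% of promoters open in changed lists, 43.8% of changed lists and 0.417% of unchanged ones passed, so lists of this size can miss a difference. With a density changed 3-fold, 93.8% and 1.88% passed. Simulated counts were drawn with the same mean for every gene, whatever its length. Real counts varied more, so these density rates may not hold for the data. Reads that carry the CAST/EiJ allele were not separated, and alleles were not analysed here. Where CAST/EiJ sequence differs from the reference, fewer of its reads could map, which would lower heights there, and this was not tested.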

Results

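DNase-seq maps accessible chromatin: the nuclease DNase I cuts DNA where it is not wrapped or covered by protein, and sites of frequent cutting appear as peaks. Right cerebral cortex of male B6CASTF1/J mice, the first-generation hybrids of the C57BL/6J and CAST/EiJ strains, was assayed at 18 to 20 months of age, which is old for a mouse. The series has 1 group with 2 biological replicates, so no comparison between conditions exists, and the spread between the 2 libraries is the error for each value. The shorter of the authors' lists held 95463 peaks covering 18.9 Mb in replicate 1 and 95284 peaks covering 20.1 Mb in replicate 2. The authors' median peak height, a depth-scaled signal, was 1.08 in replicate 1 and 1.40 in replicate 2, at a median width of 200 bp in both. Heights rose in steps of 0.00727 in replicate 1 and 0.00812 in replicate 2, so that the median peak held 148 and 173 steps. If 1 step were 1 DNase cut, which the sources used here do not state, counting error at the median height would be 8.22% and 7.60%. Genome positions are on mouse build mm10 (GRCm38), counted from 1.

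The question of the first comparison was how far the accessible elements of the tissue recurred between the replicates. The 5 shared elements with the greatest heights lay in the ribosomal RNA gene CT010467.1 (chromosome 17, 39846781 to 39846900, an exon), in the 3' UTR of Lars2, which encodes mitochondrial leucyl-tRNA synthetase (chromosome 9, 123461881 to 123462120), in an intron of Il31ra (chromosome 13, 112578161 to 112578320), at the divergent starts of Trpm8 and Hjurp (chromosome 1, 88277541 to 88277760) and between genes on chromosome 3 (5860361 to 5860530). Their mean heights were 85.8 ± 35.2, 53.7 ± 24.3, 44.6 ± 21.5, 42.6 ± 14.1 and 41.7 ± 13.9 (SD, n = 2). Across the lists, 77.2% of replicate 1 peaks (73707) overlapped a replicate 2 peak by at least 1 bp, and 77.1% of replicate 2 peaks (73421) overlapped a replicate 1 peak. Lists shifted at random along each chromosome overlapped at 1.48% ± 0.0474 and 1.49% ± 0.0493 (SD over 100 shifts). The base pairs in common made up 53.2% of the base pairs covered by either list.

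Merging both lists gave 114968 elements, of which 71810 were shared, 21639 were present in replicate 1 only and 21519 in replicate 2 only. Of the elements seen in 1 replicate only, 49.2% of those from replicate 1 and 60.9% of those from replicate 2 overlapped the authors' longer list of the other replicate. Sharing followed height: 37.4% of the lowest 10% of replicate 1 peaks and 99.6% of the highest 10% were shared, against 38.6% and 99.8% in replicate 2. The greatest height among elements seen in replicate 1 only was 15.6, at an intergenic site of chromosome X (143482981 to 143483140) that lay 35530 bp from the nearest start, that of Pak3, and 35220 bp from the nearest replicate 2 peak. The next were promoter peaks of Ephb3, an ephrin receptor (chromosome 16, 21204561 to 21204800, height 11.1), and Tarbp2, a partner of Dicer (chromosome 15, 102518281 to 102518500, height 9.51). The 3 with the greatest heights in replicate 2 only were promoter peaks of Ephb3 (chromosome 16, 21204481 to 21204560, height 17.2), of an alternative start of Slc39a10, a zinc transporter (chromosome 1, 46853601 to 46853680, height 14.4), and of Evi5l (chromosome 8, 4166381 to 4166600, height 12.8). All 5 of these promoter peaks lay 0 to 60 bp from a peak of the other replicate, so they differ in where the peak was placed and not in whether the promoter had a peak.

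**Figure D1:**
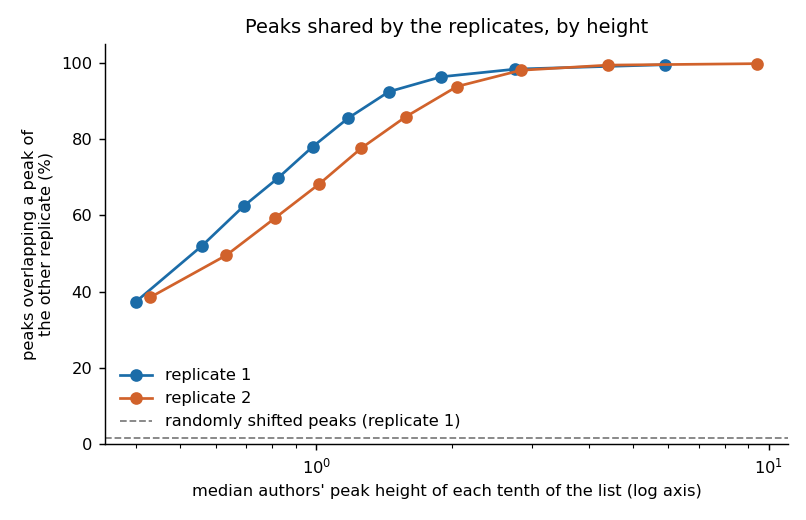
Percentage of peaks that overlap a peak of the other replicate (vertical axis) against the median height of each 10% of the list (horizontal log axis), with 1 line per replicate. Sharing climbs from 37.4% and 38.6% in the lowest 10% to 99.6% and 99.8% in the highest, and the dashed line marks the 1.48% of randomly shifted peaks.

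Heights of the 71810 shared elements correlated between the replicates on the log2 scale (Pearson r = 0.918, Spearman rho = 0.894). This correlation is across elements of 2 libraries, and elements are not independent replicates. Promoter elements tracked each other more closely (Pearson r = 0.971 over 19430 elements) than elements elsewhere (0.855 over 52380). Heights were greater in replicate 2 by a median of 0.52 on the log2 scale, 0.64 at promoters and 0.43 elsewhere. This shift enters the SD of each height below.

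The next comparison asked where in the genome the accessible elements lay. Promoters, taken as 500 bp on either side of any annotated start of a protein-coding gene, held 23.4% of replicate 1 peaks (95% exact binomial interval 23.2 to 23.7) and 24.9% of replicate 2 peaks (24.7 to 25.2), a mean of 24.2% ± 1.07 (SD, n = 2). Randomly shifted peaks reached promoters at 2.47% and 2.52%. By peak centre, introns outside promoter windows held 38.3% and 37.3% of each list and intergenic DNA 32.3% and 30.5%, against 40.7% and 52.8% (52.6% in replicate 2) for shifted peaks. Coding exons held 2.12% and 2.77% and 3' UTRs 1.34% and 1.58%.

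Promoter peaks were higher than the rest. The median promoter height was 2.13 against 0.953 elsewhere in replicate 1, and 2.93 against 1.19 in replicate 2, a ratio of 2.35 ± 0.155 (SD, n = 2). Of promoter peaks, 89.8% and 84.6% were shared between the replicates, against 73.4% and 74.5% of other peaks. Sharing rose with height, and promoter peaks were not compared with other peaks of equal height. The greatest promoter heights over all protein-coding genes were those of Hjurp and Trpm8, which share 1 peak (42.6 ± 14.1), then Gm21887 near the end of chromosome X (28.0 ± 0.352), Bahcc1 (26.9 ± 7.63), Dynlt1b, a dynein light chain (26.1 ± 12.4), and the pair 1700123O20Rik and Acin1, which share 1 peak (25.5 ± 13.1). Dnpep, an aspartyl aminopeptidase (24.9 ± 6.16), Rsph1, a radial spoke protein of cilia (23.9 ± 9.97), and Ankhd1 (23.7 ± 6.90) completed the 10 (SD, n = 2).

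The following comparison asked which cell types and pathways had accessible promoters. Of 21884 protein-coding genes, 13461 (61.5%) had a promoter peak in both replicates, 62.2% in replicate 1 and 64.4% in replicate 2. Of the 32 gene lists fixed before the data were examined, 12 had more open promoters than other genes and 12 had fewer (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 32 lists). These tests run over genes, which are not replicates, and describe these 2 libraries.

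The lists of neurons in general, of cortical excitatory neurons and of upper layers were fully open. All 14 pan-neuronal genes (adjusted exact p = 0.00283), all 15 genes of cortical excitatory neurons (adjusted exact p = 0.00171) and all 12 of upper cortical layers (adjusted exact p = 0.00787) had a promoter peak in both replicates. Among pan-neuronal genes the greatest promoter heights were those of Syt1, the calcium sensor of transmitter release (chromosome 10, 108497650 to 109010982, 8.11 ± 1.32), the neuronal tubulin Tubb3 (6.74 ± 1.69) and the dendritic protein Map2 (5.53 ± 1.52). Excitatory neuron genes were led by the kinase subunit Camk2a (chromosome 18, 60925618 to 60988152, 6.83 ± 1.41), Nrgn, a postsynaptic calmodulin binder (6.63 ± 1.44), and Lingo1 (3.73 ± 0.296). Upper layer genes were led by the transcription factor Pou3f3 (11.9 ± 1.90), the netrin receptor Unc5d (5.75 ± 1.51) and the transcription factor Lhx2 (5.15 ± 2.42). Of the 13 genes of deep cortical layers, 11 were open, which did not pass (adjusted exact p = 0.179), although in replicate 2 alone all 13 were open and the list passed. Its corepressor Tle4 had the greatest promoter height of the named list members (chromosome 19, 14448150 to 14598051, 17.2 in replicate 1 and 28.7 in replicate 2), followed within that list by Nfia (10.1 ± 2.83), whose peak is shared with E130114P18Rik, and Pcp4 (6.85 ± 3.55). All heights are means with SD, n = 2.

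Lists of neuronal function were fully open as well. The 17 genes of the synaptic vesicle cycle (adjusted exact p = 0.00115), the 21 glutamate and GABA receptor genes (adjusted exact p = 0.000194) and the 18 voltage-gated channel genes (adjusted exact p = 0.000705) all had a promoter peak in both replicates. Rab3a, a small GTPase of synaptic vesicles, reached 11.6 ± 1.06, Syn2 9.20 ± 2.76, and the receptor subunits Gabbr1 7.60 ± 2.49, Grin1 7.29 ± 3.58 and Gria2 5.49 ± 1.53. The calcium channel subunits Cacna1a and Cacna1g reached 7.40 ± 2.33 and 6.06 ± 2.95 and the potassium channel Kcnq3 5.87 ± 2.08. All 18 immediate early genes, which neurons induce on activity, were open (adjusted exact p = 0.000705), with Jun at 15.7 ± 3.49, Arc at 10.1 in replicate 1 and 14.0 in replicate 2 and Homer1 at 10.2 and 13.9. All 19 circadian clock genes were open too (adjusted exact p = 0.000497). Per1 at 19.2 ± 5.60, Nr1d1 at 18.7 ± 7.18 and Tef at 18.4 ± 5.62 had heights above those of each named synaptic gene (SD, n = 2). Against genes matched on promoter CpG content, of which 88.2%, 83.3% and 89.5% were open, the synaptic vesicle cycle (adjusted permutation p = 0.163), immediate early genes (adjusted permutation p = 0.110) and the circadian clock (adjusted permutation p = 0.220) no longer passed.

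Housekeeping lists were fully open: 28 of 28 ribosomal protein genes (adjusted exact p = 1.26e-05), 23 of 23 genes of oxidative phosphorylation (adjusted exact p = 7.39e-05) and 19 of 19 cell cycle genes (adjusted exact p = 0.000497). Rpl15 (14.7 ± 3.01, a peak shared with Nkiras1) and Rps2 (14.5 ± 4.22) led the ribosomal proteins, and cytochrome c (Cycs, 15.7 ± 4.88), Ndufv1 (14.0 ± 3.70) and Ndufb5 (13.4 ± 4.76, a peak shared with Mrpl47) the respiratory chain. The mitotic kinesin Kif11 (17.6 ± 4.77), the replication helicase subunit Mcm5 (14.4 ± 5.40) and the kinetochore protein Cenpf (12.3 ± 3.46) led the cell cycle list (SD, n = 2). Against genes matched on promoter CpG content, of which 91.3% and 94.7% were open, oxidative phosphorylation (adjusted permutation p = 0.254) and the cell cycle (adjusted permutation p = 0.483) no longer passed.

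Glial lists and inhibitory neurons divided. Of 16 astrocyte genes, 15 were open (adjusted exact p = 0.0111), with Clu (7.32 in replicate 1 and 12.7 in replicate 2), glutamine synthetase (Glul, 7.81 ± 1.34, a peak shared with Teddm2) and Aldoc (4.60 ± 0.814) highest, and Aqp4, the water channel of astrocyte end feet, without a promoter peak in either replicate. The astrocyte list did not pass in the higher 50% of peaks, with basic transcript starts or where the peaks of the replicates had to overlap each other. Among oligodendrocyte genes 13 of 18 were open (adjusted exact p = 0.518), with Olig1 (4.09 ± 0.530), myelin basic protein (Mbp, 2.90 ± 1.06) and Myrf (2.46 ± 0.848) highest and Aspa without a peak. Oligodendrocyte precursor genes were open in 8 of 12 (adjusted exact p = 0.829), led by Tnr (3.33 in replicate 1 and 4.32 in replicate 2) and Pdgfra (3.51 ± 1.46), and Bmp4 and Gpr17 had no peak. Genes of inhibitory neurons were open in 11 of 19 (adjusted exact p = 0.841). In each replicate alone 73.7% of them were open, against 62.2% and 64.4% of all genes, but not always the same ones. Maf (3.11 ± 0.427), Cck (2.96 ± 1.47) and Adarb2 (2.11 ± 0.0963) were highest there, and Dlx2 and Vip had no promoter peak (SD, n = 2).

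Genes of microglia and of vessel, meningeal, ependymal and blood cells had fewer open promoters. Microglia had 4 of 19 (adjusted exact p = 0.00112), endothelial cells 4 of 16 (adjusted exact p = 0.00670), mural cells 3 of 12 (adjusted exact p = 0.0192), meningeal fibroblasts 3 of 13 and ependyma and choroid plexus 3 of 13 (adjusted exact p = 0.0108 for each), and blood cells 1 of 15 (adjusted exact p = 7.39e-05). Irf8 (2.63 ± 0.628) and Sall1 (2.30 ± 0.727) were among the highest of microglia, while the complement genes C1qa and C1qb had no promoter peak. The glucose transporter Slc2a1 (5.40 ± 1.06), Kdr (1.24 ± 0.118) and Abcb1a (0.694 ± 0.190) led the endothelial genes, and Cdh5 and Cldn5, both of endothelial junctions, had none. Rgs5 (0.887 ± 0.112), Kcnj8 (0.782 ± 0.490) and Myh11 (0.782 ± 0.376) led mural cells, where Acta2 and Anpep had none. Col1a1 (3.74 ± 2.12), Foxc1 (1.93 ± 1.02) and Ptgds (1.65 ± 0.0126) led the fibroblast list, where Col1a2 and Col3a1 had none. Foxj1, the master regulator of motile cilia (10.1 ± 5.08), Dynlrb2 (7.66 ± 1.86) and Pifo (1.27 ± 0.305) were the 3 open ependymal genes, and Ccdc153 and Clic6 had none. Of blood cell genes, Alas2 had none. Against genes matched on promoter CpG content, 6 of the 12 lists with fewer open promoters no longer passed, among them microglia (adjusted permutation p = 0.216), mural cells (adjusted permutation p = 0.134), meningeal fibroblasts (adjusted permutation p = 0.196), ependyma and choroid plexus (adjusted permutation p = 0.152) and blood cells (adjusted permutation p = 0.163). In replicate 2 alone, which leaves out replicate 1, ependyma and choroid plexus (38.5% open) and mural cells did not pass either, and microglia rose to 36.8% open. With 1000 bp on either side, endothelial cells and mural cells did not pass.

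Genes of other tissues and regions also had fewer open promoters. None of 19 liver genes had a promoter peak in both replicates (adjusted exact p = 2.09e-07), with Ahsg and albumin (Alb) among those closed in both. Skeletal and heart muscle had 1 of 19 (adjusted exact p = 4.38e-06), which was Tnnt2 (0.954 ± 0.156), and Acta1 and Actn3 had none. Germline genes were open in 2 of 18 (adjusted exact p = 7.39e-05), Gdf9 (14.7 ± 3.67, a peak shared with the respiratory gene Uqcrq) and Dazl (2.86 ± 0.418), and Ddx4 and Mael had none. Skin and gut epithelium had 3 of 17 (adjusted exact p = 0.000705; matched on CpG content, adjusted permutation p = 0.152), Krt10 (6.98 ± 1.79), Lgr5 (2.16 ± 1.05) and Krt1 (1.72 ± 0.937), and the gut factors Cdx1 and Cdx2 had none. Hox genes, which pattern the trunk and hindbrain, were open in 2 of 33 (adjusted exact p = 9.01e-10), Hoxa7 (2.77 ± 1.61) and Hoxc5 (1.07 ± 0.257), and Hoxa11 and Hoxa13 had none. Genes that mark other brain regions were open in 9 of 27 (adjusted exact p = 0.00765), led by Ppp1r1b (3.65 ± 0.506) and the dopamine receptor Drd1 (3.63 ± 1.41), both abundant in striatum, and Prox1 (1.70 ± 0.528), with En1 and Fev without a peak (SD, n = 2). In replicate 2 alone, 27.8% of germline genes and 15.2% of Hox genes were open, against 11.1% and 6.06% in both replicates.

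The remaining lists did not pass against all other genes. Forebrain regional factors were open in 11 of 14 (adjusted exact p = 0.312), led by Id2 (11.8 ± 2.65), Lmo4 (7.78 ± 1.76) and Lhx2, with Nr2f2 closed. Neural progenitor genes were open in 13 of 16 (adjusted exact p = 0.156), led by Hes1 (3.31 in replicate 1 and 6.07 in replicate 2), with Sox2 (2.91 ± 0.145) also among the highest, while Eomes and Nes had no promoter peak. Genes of inflammation and ageing were open in 14 of 22 (adjusted exact p = 1). Stat3 (13.1 ± 5.29), H2-D1 (9.78 ± 4.87) and Nfkbia (5.77 ± 2.95) were highest, and C3 and Cst7, both raised in reactive glia, had none. Imprinted genes were open in 16 of 19 (adjusted exact p = 0.0725), led by Ube3a (7.74 in replicate 1 and 14.2 in replicate 2), Zim1 (5.92 ± 1.77) and Peg3 (5.52 ± 1.42, a peak shared with Usp29), and Kcnq1 and Ndn had none (SD, n = 2). Other settings brought some of these past the threshold: forebrain regional factors with 1000 bp on either side and in replicate 2 alone (92.9% open), and imprinted genes with 250 bp and in replicate 2 alone (89.5% open). Genes of inflammation and ageing passed against genes matched on promoter CpG content, of which 40.9% were open (adjusted permutation p = 0.0411).

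**Figure D2:**
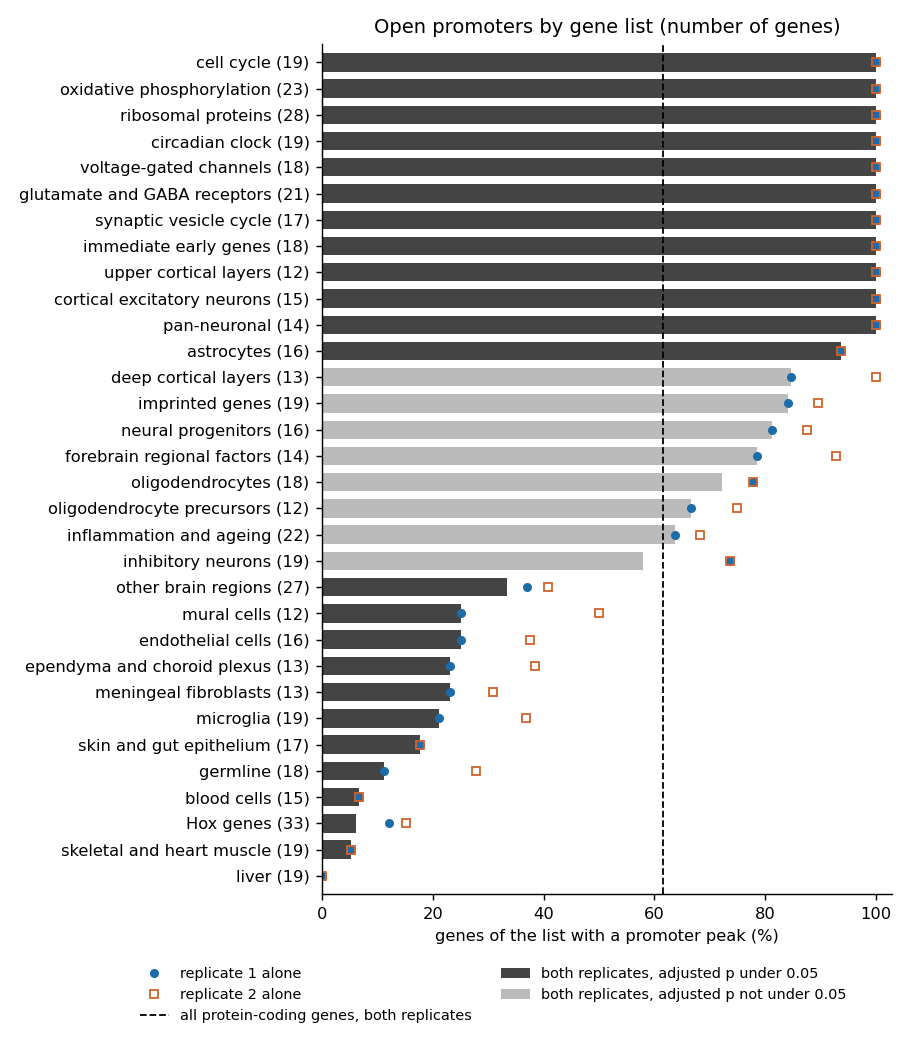
Percentage of the genes of each list with a promoter peak in both replicates (bars, dark where the adjusted p is under 0.05) and in each replicate alone (circles and squares), with the number of genes in parentheses. The dashed line is the 61.5% of all protein-coding genes, which 12 lists exceed and 12 fall short of past the threshold.

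The comparison of distal elements asked which genes were surrounded by accessible elements away from promoters. Distal elements were the 52380 shared elements outside promoters, counted within the gene body and 10 kb on either side. A gene had a median of 1 such element, and 59.7% of genes had at least 1. Of the 32 lists, 9 had a higher density than 10000 random lists matched on length and 0 a lower one (two-sided rank test, Benjamini-Hochberg adjusted; 0.0002 is the smallest unadjusted p that the random lists can give). Where the median of the matched lists was 0, a lower density could not pass. That was so for blood cells, where 12 of 15 genes had no distal element, Hox genes, ribosomal proteins and oxidative phosphorylation. Immediate early genes had a median of 1.32 elements per 10 kb against 0.0868 in matched lists, cortical excitatory neurons 0.810 against 0.221, astrocytes 0.739 against 0.199, circadian clock genes 0.675 against 0.193, pan-neuronal genes 0.664 against 0.203 and voltage-gated channels 0.550 against 0.218 (adjusted permutation p = 0.00107 for each of these 6). Forebrain regional factors followed at 0.672 against 0.188 (adjusted permutation p = 0.00366), oligodendrocytes at 0.576 against 0.211 (adjusted permutation p = 0.00480) and neural progenitors at 0.593 against 0.0921 (adjusted permutation p = 0.00640). The random lists were matched on length alone, not on promoter CpG content or on whether the promoter was open.

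Among the named genes, Arc, whose protein acts at synapses after activity, had 7 distal elements in both replicates (14 in replicate 1 and 7 in replicate 2) around a short gene body (chromosome 15, 74669083 to 74672570), and Fosb had 7 (7 and 7). The splicing factor gene Rbfox3, which encodes the neuronal marker NeuN, had 30 (35 and 52), Celf4 28 (35 and 32), Lingo1 19 (25 and 28) and Grin2b 11 (17 and 14). Of glial genes, Aldh1l1 had 12 (13 and 13), the glutamate transporter Slc1a3 9 (9 and 10), Mbp 13 (13 and 21) and Mobp 6 (6 and 7). Aldh1l1 and Slc1a3 had low promoter peaks (0.982 ± 0.207 and 0.902 ± 0.298, SD, n = 2), and Mobp had a promoter peak in replicate 2 only. Rora had 33 distal elements (42 and 42), Arntl, which encodes the clock protein BMAL1, 10 (15 and 11), Cacna1c 32 (43 and 40) and Kcnma1 28 (39 and 33). Bcl11a had 7 (10 and 17), Tbr1 7 (9 and 12) and Notch1 6 (7 and 10).

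The other lists did not pass, in either direction. Synaptic vesicle cycle genes had 0.419 elements per 10 kb (adjusted permutation p = 0.0803), with Bsn and Syt1 at 10 each (11 and 14, and 17 and 16), and skin and gut epithelium had 0.409 (adjusted permutation p = 0.0803), with Tff3 at 4 (4 and 5) and Trp63 at 3 (5 and 3). Glutamate and GABA receptors had 0.192 (adjusted permutation p = 0.772) despite 28 elements at Gabbr2 (41 and 30) and 17 at Grin2a (31 and 21). Upper layers had 0.284 (adjusted permutation p = 0.635; Cux1 14, from 21 and 18, and Unc5d 14, from 18 and 19), deep layers 0.259 (adjusted permutation p = 0.772; Sox5 22, from 26 and 32, and Foxp1 16, from 19 and 25) and inhibitory neurons 0.0639 (adjusted permutation p = 0.691; Erbb4 7, from 9 and 9, and Nxph1 4, from 6 and 5). Microglia had 0.373 (adjusted permutation p = 0.207) with 12 elements at Cx3cr1 (12 and 20) and 3 at C1qb (4 and 3), although neither promoter had a peak in both replicates. Endothelial cells had 0.321 (adjusted permutation p = 0.426), with 8 at Erg (12 and 8) and 8 at Pecam1 (10 and 9), also without a promoter peak in both. Oligodendrocyte precursors had 0.276 (adjusted permutation p = 0.664; Tnr 18, from 29 and 24, and Lhfpl3 7, from 10 and 11) and mural cells 0.401 (adjusted permutation p = 0.207; Cspg4 5, from 9 and 8, and Myh11 5, from 6 and 5).

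The lists of other tissues did not pass either. For blood cells the median of matched lists was 0, so a lack of distal elements there could not be detected. Liver had 0.280 against 0.177 in matched lists (adjusted permutation p = 0.772; Cps1 3 and Hnf4a 3), muscle 0.442 against 0.194 (adjusted permutation p = 0.118; Acta1 3 and Ckm 3), germline 0.0351 against 0.175 (adjusted permutation p = 0.659; Mael 2 and Nanog 2), blood cells 0 (adjusted permutation p = 1; Cd3e 2), meningeal fibroblasts 0.172 (adjusted permutation p = 1; Slc6a13 3 and Col1a1 2) and ependyma and choroid plexus 0.265 (adjusted permutation p = 0.839; Kl 3 and Clic6 2, from 2 and 4). Other brain regions had 0.158 (adjusted permutation p = 0.859; Pax5 8 and Tcf7l2 6, from 12 and 9) and Hox genes 0.364 against 0 (adjusted permutation p = 0.219; Hoxa13 2 and Hoxb6 2). Ribosomal proteins had 0.373 against 0 (adjusted permutation p = 0.292; Rps14 8 and Rpl3 5), oxidative phosphorylation 0.343 against 0 (adjusted permutation p = 0.372; Sdhb 4 and Atp5b 3), the cell cycle 0.158 (adjusted permutation p = 0.859; Aurkb 9 and Mcm5 5), inflammation and ageing 0.203 (adjusted permutation p = 0.772; Apoe 2) and imprinted genes 0.406 (adjusted permutation p = 0.168; Kcnq1 10 and Igf2r 6). With the gene body alone, oligodendrocytes (adjusted permutation p = 0.138), forebrain regional factors (adjusted permutation p = 0.115) and neural progenitors (a median of 0, adjusted permutation p = 1) no longer passed. With 50 kb on either side, those 3 and astrocytes (adjusted permutation p = 0.336) did not pass, and astrocytes did not pass on the higher peaks alone (adjusted permutation p = 0.228). Synaptic vesicle cycle genes passed with 50 kb on either side, on the higher peaks alone, with basic transcript starts and in replicate 1 alone, where muscle passed too (0.725 per 10 kb). With basic transcript starts, skin and gut epithelium and imprinted genes passed as well. In single replicates the densities of inhibitory neurons (0.187 and 0.412) and germline genes (0.276 and 0.343) exceeded those of shared elements by more than 1.5 times. In 1 of the replicates or both, so did forebrain regional factors (1.10 in replicate 2), neural progenitors (1.10 in replicate 2), the cell cycle (0.306 and 0.268), glutamate and GABA receptors (0.354 in replicate 1), inflammation and ageing (0.387 in replicate 1), other brain regions (0.378 in replicate 2) and meningeal fibroblasts (0.299 in replicate 2).

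**Figure D3:**
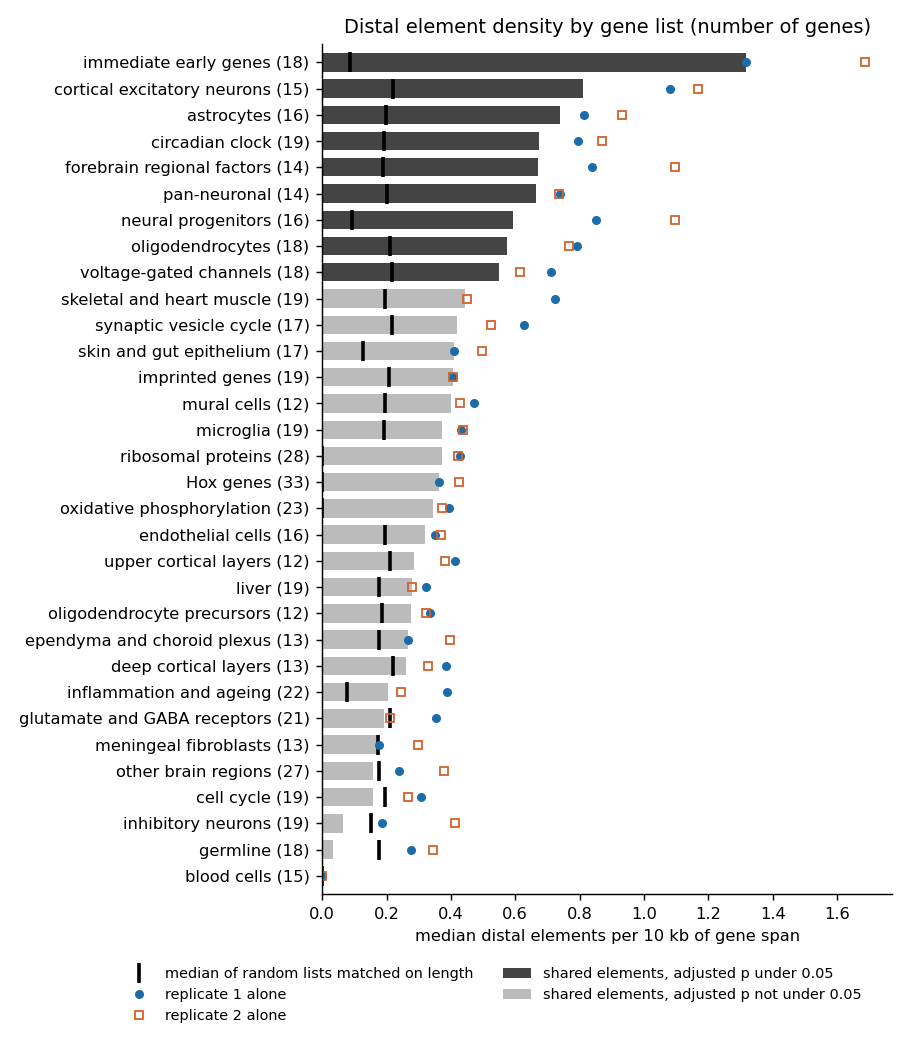
Median number of distal elements per 10 kb of gene span for each list, for elements shared by both replicates (bars, dark where the adjusted p is under 0.05) and for each replicate alone (circles and squares). Black ticks mark the median of random lists matched on length; immediate early genes stand at 1.32 against 0.0868.

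Over all protein-coding genes, the largest numbers of distal elements belonged to long genes. Gm20388, an annotated span on chromosome 8 (119910841 to 124345722) that runs across many other genes, had 267 (315 and 363), and Fgfr2, whose annotated span on chromosome 7 also runs across other genes (130162451 to 133123350), had 104 (134 and 145). Asic2, an acid-sensing ion channel, followed with 58 (78 and 65), Gse1 with 53 (60 and 67), the calmodulin-binding transcription activator Camta1 with 49 (58 and 71) and Gm37240 with 49 (78 and 69). Auts2 had 44 (60 and 56), the guanine nucleotide exchange factor gene Kalrn 42 (45 and 51) and Csmd1 41 (71 and 48). Per 10 kb, among genes with at least 10 elements, Cdk5r1, the neuronal activator of CDK5, ranked highest with 4.14, followed by Tspan17 with 3.65, Trim7 with 2.60, Setd1b with 2.58, Bahcc1 and Inf2 with 2.14 each, and then by, among others, the kainate receptor subunit Grik5 with 2.06, and Rhof and Mef2d with 2.01 each. Counts in single replicates exceeded 1.5 times the shared count at Cdk5r1 (16 in replicate 1 against 10) and Rhof (20 in replicate 2 against 10).

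Footprints, short stretches protected from cutting inside accessible DNA, were taken from the authors' calls. Replicate 1 had 332304 footprints with a median width of 9 bp and replicate 2 had 385764 with a median of 10 bp. Of these, 69.5% and 66.2% lay wholly inside a peak of the same replicate (67.8% ± 2.35, SD, n = 2), 27.8% and 30.6% lay in promoter windows, and 87.3% and 86.8% of peaks held at least 1. By at least 1 bp, 52.6% of replicate 1 footprints and 43.4% of replicate 2 footprints overlapped a footprint of the other replicate. Inside peaks these shares were 54.0% and 46.6%, against 35.2% ± 0.0798 and 31.4% ± 0.0766 for footprints moved at random within the same peaks (SD over 100 shifts).

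The last comparison of the footprints asked which transcription factors' consensus sites they held. Of 28 consensus sequences, 16 were found more often in footprints than in equally wide windows of the same peaks that touched no footprint in both replicates, 5 less often in both, and 7 passed in neither direction in both (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 28, in each replicate). Of footprints inside peaks, 217511 of 230900 in replicate 1 and 229361 of 255215 in replicate 2 had a control window and were compared. The site of CTCF, an insulator protein, lay in 1.58% and 1.01% of these. That was 287 times (exact 95% interval 164 to 556) and 165 times (98.2 to 302) as often as in control windows. Over all footprints inside peaks the CTCF site lay in 2.01% and 1.76%, so the footprints left out held it more often. The site of NRF1, a regulator of mitochondrial and growth genes, lay in 0.126% and 0.102% of the footprints compared. None of the replicate 1 control windows held it, so the ratio there was at least 91.7, taking 3 counts as the floor, and in replicate 2 it was 117 (32.0 to 972, from 2 control windows). The NFI site lay in 0.0202% and 0.0148% of footprints, 44.0 times as often as in controls in replicate 1 (7.50 to 1777, from 1 control window) and at least 11.3 times in replicate 2. EGR, the family of the activity-induced gene Egr1, had ratios of 34.8 (18.1 to 76.8) and 26.4 (14.9 to 51.7), and CREB, another factor of activity-dependent transcription, 20.8 (14.4 to 31.1) and 25.2 (16.2 to 41.7). RFX had 23.8 (12.7 to 50.3) and 13.3 (7.42 to 26.3), SP/KLF 11.8 (10.4 to 13.5) and 12.1 (10.6 to 13.8), and YY1 19.2 (8.54 to 53.3) and 3.81 (2.48 to 6.06). The YY1 odds in replicate 1 rested on 6 control windows and fell to 3.89 without padding and 2.89 with 10 bp, close to the 3.32 and 2.49 of replicate 2. These intervals cover counting error only. Footprints held more GC than control windows (58.4% against 53.6% and 60.3% against 54.5%), and against shuffled bases of the same footprints the odds ratio of EGR was 2.94 and 2.44 and that of SP/KLF 5.05 and 4.54. The size of the odds followed the setting: those of CTCF in replicate 2 were 804 without padding and 48.3 with 10 bp of padding, and those of NRF1, EGR, CREB, RFX and SP/KLF also fell by more than 1.5 times from no padding to 10 bp. The E box CACGTG, AP-1, the bHLH sites CAGATG and CAGCTG, ZNF143, ETS, T-box and NFY were also found more often, with odds ratios of 3.03 and 3.18 for the E box, 2.57 and 2.07 for AP-1 and 2.24 and 2.06 for CAGATG. Against shuffled bases these were 2.55 and 2.25 for the E box, 12.1 and 9.17 for AP-1 and 5.27 and 4.89 for CAGATG. Control windows held AP-1 (0.635% and 0.624%) and CAGATG (1.58% and 1.55%) more often than shuffled bases did (0.131% and 0.136%, 0.682% and 0.680%). The greater odds of AP-1 and CAGATG against shuffled bases are therefore not particular to footprints. NFY did not pass without padding, and T-box did not pass in both replicates without padding, with 10 bp of padding or on shared footprints. SOX, the homeobox site TAATTA, SPI1, POU and GATA were found less often, and REST, NR4A, MEF2, RUNX, TEAD, HNF4 and HNF1 did not pass in both replicates. SPI1 did not pass in replicate 1 with 10 bp of padding, while RUNX and TEAD without padding, and TEAD on shared footprints, were found less often in both.

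The sites of blood and liver factors were not found more often in footprints than in control windows. The GATA site lay in 0.0782% and 0.0693% of footprints against 0.235% and 0.216% of control windows, the lowest odds of the 28 in both replicates together (adjusted exact p = 2.43e-40 and 1.22e-40). HNF4 lay in 0.0120% against 0.0129% and in 0.0153% against 0.0161% (adjusted exact p = 0.999 and 0.940). HNF1 was found in 0 footprints of either replicate and in 0 and 1 control windows, too few to compare. Against shuffled bases of the same footprints, 4 of the 5 sequences found less often no longer were, with SOX, SPI1 and POU turning to more often. HNF4 (odds ratios 1.97 and 2.17, adjusted exact p = 0.0357 and 0.00449), TEAD and MEF2 were found more often than in shuffled bases too. Shuffling kept only the base composition, and control windows also held HNF4 more often than shuffled bases (0.0129% and 0.0161% against 0.00693% and 0.00784%). The same held for SOX, SPI1, POU, TEAD and MEF2, so these results against shuffled bases are not particular to footprints.

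**Figure D4:**
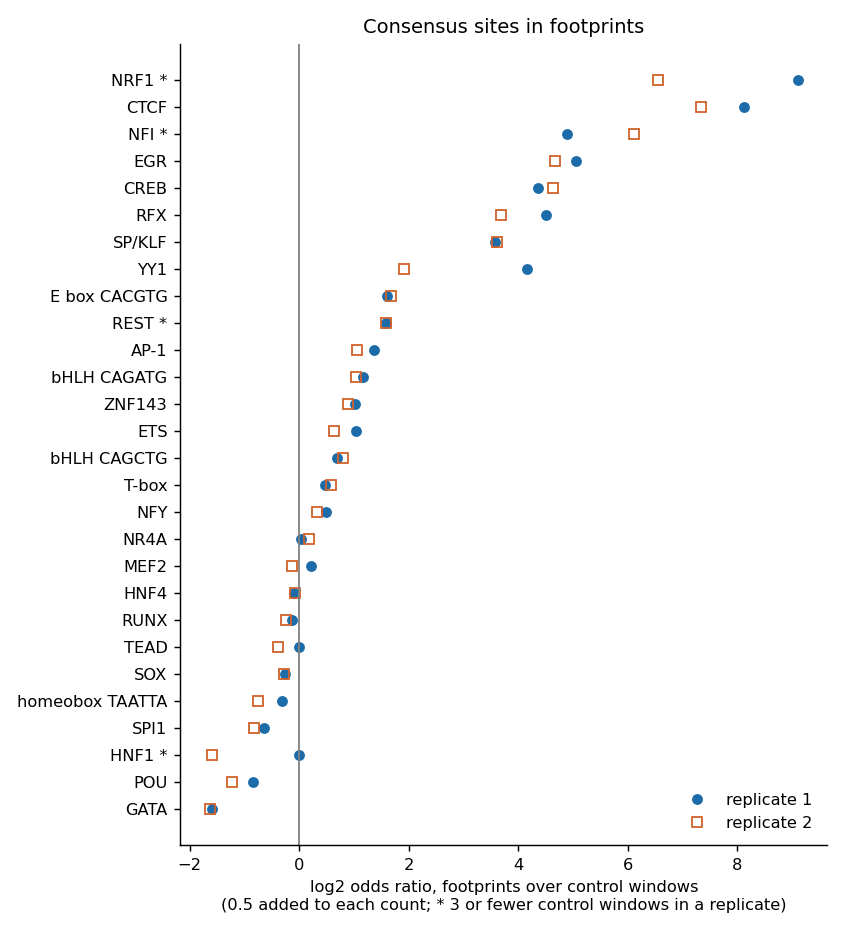
Log2 odds ratio of each consensus sequence in footprints over control windows of the same peaks, with filled circles for replicate 1 and open squares for replicate 2; an asterisk marks sequences found in 3 or fewer control windows in a replicate, whose odds rest on the 0.5 added to each count. NRF1 and CTCF lie farthest right and GATA farthest left.

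The sex chromosomes were compared with the autosomes, since male cells carry 1 X and 1 Y. Chromosome X held 14.4 peaks per Mb in replicate 1 and 12.9 in replicate 2, below the autosomes' range of 30.1 (chromosome 3) to 53.0 (chromosome 11) and 28.5 to 55.7. Relative to the autosomal median X stood at 0.355 ± 0.0353 (SD, n = 2). Its peaks were lower too, with a median height of 0.654 against 1.08 for the median autosome in replicate 1 and 0.893 against 1.43 in replicate 2. Chromosome Y held 37 and 26 peaks, or 0.403 and 0.283 per Mb.

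**Figure D5:**
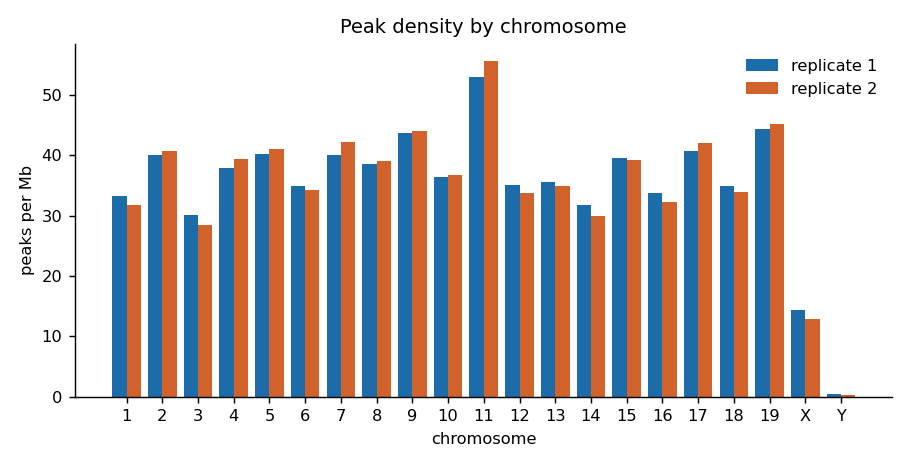
Peaks per Mb of each chromosome, with 1 bar per replicate. Chromosome X stands at 14.4 and 12.9 and every autosome at 28.5 or more, while Y holds 0.403 and 0.283.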

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

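The test of GC content at the distinct elements near Hox genes, the pooled test of CpG content and the errors of medians before and after removal of the GC trend were chosen after the result was seen, and the other tests of this part before.

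Part of the deposited data lay outside the longer peak list. Stretches with a false discovery rate up to 0.05 covered 17.7 Mb outside the longer peak list in replicate 1 and 22.3 Mb in replicate 2. Footprints that touched no peak of the longer list numbered 30695 and 52875, or 9.24% and 13.7% of all footprints. Peaks of the shorter list outside the longer list numbered 1056 and 1206, with median heights of 0.553 and 0.646, and 72.1% and 69.9% of them lay within 200 bp of a peak of the longer list.

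Distal elements of 3 lists departed from the trend of the height ratio between the replicates beyond random lists. Against elements of equal height, the log2 ratio of replicate 2 over replicate 1 was higher near astrocyte genes (0.37, adjusted permutation p = 0.0107) and Hox genes (0.59, adjusted permutation p = 0.00320) and lower near glutamate and GABA receptor genes (-0.29, adjusted permutation p = 0.00320; raw median 0.16, so heights were greater in replicate 2 there too). After the trend with GC content was removed, 1 of the 3, the Hox genes, still passed; the astrocyte median moved from 0.37 (bootstrap SE 0.164) to 0.28 (0.108) and the receptor median from -0.29 (0.0740) to -0.14 (0.0502), the first with most of its difference left, so GC content as the cause stays open. A different mixture of cell types had been predicted to move at least 1 cell type list up and another down, with promoters of the same sign. Only the astrocyte list passed, and its promoters had a median log2 ratio of -0.048 (SE 0.107, 6 of 14 positive). The prediction was not met, but with 1 list and a promoter median smaller than its SE, a mixture is not excluded. The Hox difference rested on 12 distinct elements, which neighbouring genes share, so the list p counted some more than once. Their median was 0.49 before and 0.56 after removal of the GC trend, outside the range of random sets (-0.31 to 0.34). Random sets came from the whole genome, while these elements belong to a list picked for its difference and lie in clusters, so that range says little. Since the median did not fall, GC content is unlikely to be the cause over the set. At Hoxa the median did fall, from 0.13 to -0.02. No biological explanation was tested.

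Chromosome X had fewer peaks per Mb than every autosome. CpG-rich promoter peaks on X stood at 0.549 of the autosomal median height in replicate 1 (bootstrap 95% interval 0.489 to 0.595) and 0.536 in replicate 2 (0.460 to 0.580). This is consistent with the single X of male cells, which offers less template per cell than a pair of autosomes. Fewer genes on X could account for part of the lower density but not for all of it. Peaks per protein-coding gene on X were 0.551 of the autosomal median in replicate 1 and 0.499 in replicate 2, below every autosome. Per Mb these values were 0.380 and 0.330. The lowest autosome per gene was chromosome 7, at 2.88 against 2.59 on X in replicate 1 and 3.04 against 2.32 in replicate 2. No biological explanation beyond copy number was tested.

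Of the 12 lists with fewer open promoters, 6 remained below genes matched on promoter CpG content, among them Hox, liver, muscle and germline genes. Hox genes and genes of other brain regions did not have low CpG content at the outermost start. Their median CpG observed over expected was 0.689 and 0.679, against 0.552 over all genes. Genes matched to them were open in 84.8% and 77.8%, above the 61.5% of all genes, which argues against low CpG content as a cause for these lists. For the rest of these 6, low CpG content at the outermost start is unlikely to be the whole cause. Other starts, and the number of starts, were not matched. The other 6, microglia, mural cells, meningeal fibroblasts, ependyma and choroid plexus, blood cells, and skin and gut epithelium, did not pass one by one. Pooled, 17 of their 89 genes were open (19.1%) against 38.2% in matched genes. These lists had been picked because few promoters were open. Random matched lists put through a similar selection had 24.7%, 5.62 points more (permutation p = 0.00240). The lower limit of that selection was set from these same lists, so random lists could seldom fall below them. That comparison therefore cannot decide whether low CpG content is the whole cause here. The abundance of cell types was not measured, and whether rare cells are too few in the tissue for their promoters to be called was not tested.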

How the results depend on the processing

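No paired analysis was possible because the series has 1 group. Starts of the basic transcript set, and peaks of both replicates that overlap each other, were settings chosen after the result was seen. Of the promoter calls of lists under the alternatives, 232 stayed the same, 18 grew weaker and 6 stronger; of 192 distal calls, 177, 7 and 7, and 1 reversed; of 168 motif calls, 151, 6 and 6, and 5 reversed. Of 571 promoter heights 10 moved by more than their SD between the replicates, 7 with 1000 bp and 3 with 250 bp. Of 252 distal counts 59 moved by more than 1.5 times. With either replicate left out, summary counts stayed within 1.5 times. Heights and summary values that are means of both replicates were judged by the SD between the replicates. The mean of a pair always lies within the SD of each member, so leaving out a library could not move them. The share of peaks shared by the replicates, 77.1%, was 65.8% with 50% reciprocal overlap, 83.4% in the higher 50% of each list and 74.3% in the longer list. The correlation, 0.918, was 0.921 with reciprocal overlap and 0.855 without promoters. The share of peaks at promoters, 24.2%, was 20.2% with 250 bp, 28.6% with 1000 bp, 35.6% in the higher 50% and 20.7% with basic starts, and promoter against distal peak signal fell from a ratio of 2.35 to 1.98 with 1000 bp. Matched on CpG content, 6 and not 12 lists lay below and 8 and not 12 above. Footprints inside peaks rose from 67.8% to 85.8% with the longer list, and shared footprints fell from 48.0% to 33.5% with reciprocal overlap. The gene body alone gave neural progenitors a median of 0 distal elements. With shuffled bases as control, 1 and not 5 sequences were found less often, and mean log2 odds turned positive for HNF4 (1.05), TEAD (0.44), SOX (0.45), SPI1 (0.61) and POU (1.26). Control windows also held HNF4, TEAD, SOX, SPI1 and POU more often than shuffled bases, so this change is not particular to footprints. Wider windows and stricter overlap change these shares by construction. The cause of the lower share of shared peaks in the longer list, and of the reversed results, was not tested. Effects of depth were not tested.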

Other observations

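Of the 5 highest shared peaks, 4 lay in sequence that recurs in the genome. Their 24-mers had a median of 2 copies in the ribosomal RNA gene CT010467.1, 3 at Lars2, 4 at Il31ra and 9 at the intergenic peak of chromosome 3, while the peak at Hjurp and Trpm8 had 1. Of 200 random distal peaks, 99.5% had a median of 1 copy. None of these 24-mers occurred in the mitochondrial genome.

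Higher peaks held more footprints each. Peaks with heights below 0.5 held 0.902 footprints each in replicate 1 and 0.693 in replicate 2, and peaks above 8 held 4.99 and 4.65. The distinct distal elements near Hox genes were higher in replicate 2 in all clusters (raw median log2 1.17 in Hoxb, 1.03 in Hoxc, 1.10 in Hoxd and 0.58 in Hoxa). The medians were 0.50, 0.56, 0.54 and 0.13 after removal of the height trend, and 0.53, 0.66, 0.68 and -0.02 after removal of the GC trend too, over 2 to 4 elements each. Distal elements near immediate early genes were greater in replicate 2 by a raw median log2 of 0.49. Against elements of equal height they stood at -0.11 before removal of the GC trend (adjusted permutation p = 0.286) and -0.27 after it (adjusted permutation p = 0.0192). Bases with a false discovery rate up to 0.001 covered 28.3 and 32.6 Mb, of which 62.1% of the union was in common.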
